A study of Schmidtea mediterranea with 6 samples.

How the data were processed

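Polyadenylated RNA of sorted planarian cells was measured on 6 single-colour Agilent arrays of a custom design, 2 for each of 3 populations of *Schmidtea mediterranea* cells: X1, X2 and Xins. Per the labels' protocols, cells were separated by fluorescence-activated sorting, mRNA was taken with oligo-dT probes, and Cy3-labelled complementary RNA was made by linear amplification from an oligo-dT primer carrying a T7 promoter. The labels assign each array to a population and give it a replicate number, 1 or 2. They do not say whether replicates came from separate sorts or animals, so the p-values measure only the spread between these samples, which may be technical.

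The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction version 11.5.1.1 and its protocol GE1_1105_Oct12, per the file headers. The processed intensity had been background-subtracted and detrended within each array and not scaled between arrays, per the file headers. The mean spot intensity and the median local background intensity, also deposited, were not corrected. The files further give flags for spots well above background, saturated spots and outlier spots. All arrays lay on 1 slide and were scanned on 1 day. X1 replicate 1 and X2 replicate 1 lay in slide row 1 and the other 4 arrays in row 2. A value table of the whole series was deposited as well, with 10871 rows and 1 column per array. In 4 of its columns (X1 replicate 1, both X2 arrays and Xins replicate 1) the values the authors deposited matched the natural log of that array's own processed intensity minus a constant. Their quantiles had slopes between 1 and 1.01 against it. The columns of X1 replicate 2 and Xins replicate 2 followed none of the 6 arrays closely, with slopes of 1.06 and 1.1 against their own array and SDs of 0.2 and 0.21 between the quantiles, against 0.011 to 0.028 for the other columns. The Xins replicate 2 column came nearer to X1 replicate 2 (slope 1, SD 0.14) than to its own array, though not as near as the matching columns, so what it holds is not settled. Those 2 are taken here as a score the authors deposited, whose scale and centring stay unknown. The column medians were -0.549 and -1.47 for X1 replicates 1 and 2, -0.419 and -0.339 for X2, and 0.029 and -1.01 for Xins. The rows of this table matched no probe column of the scanner files, so it was used only as an alternative and names no probe. Its direction is that of the intensity for the 4 matching columns.

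Each array held 15744 spots, of which 536 were controls and were left out. The remaining 15208 spots carried 10871 probe names, 1 for each transcript model, but only 5519 distinct sequences, because 2750 sequences stood under several names. A probe is therefore counted here as 1 distinct sequence, and its spots were averaged on the log2 scale. On each array, the names of 1 sequence differed by an SD of 0.135 to 0.305 log2 units, against 0.135 to 0.258 between 2 spots of the same name. Outlier spots, between 0 and 55 per array, were left out, and saturated spots were kept. The transcript models belonged to 4 sets, named in the files by the prefixes dd (4288), OX (3690), mk4 (2864) and ASA (29). The files pair no probe with a gene name, and no genome or annotation was used, so gene lists drawn up before the data were examined were not tested and probes are reported by transcript model and position. Positions are those in the files, as contig, strand, start and end. Their genome build and whether they count from 0 or 1 are not given in the sources used here, and neither is whether a site lies in an exon or a 3' untranslated region. Every transcript model had 1 probe and the models were not grouped into genes, so the use of different sites of 1 gene was not compared.

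Values were log2 of the processed intensity minus the 75th percentile of each array over all probes. A probe counted as well above background on an array where a share above 0.5 of its spots were. It was tested where it was so on both arrays of at least 1 population, which left 2296 probes. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 6 arrays with a mean per population and no further term. Variances were moderated by empirical Bayes without a trend, and p-values were adjusted by the method of Benjamini and Hochberg for each of 3 contrasts: X2 against X1, Xins against X1 and Xins against X2. A change was called at an adjusted p below 0.05. Precision is limited by the 2 arrays per population, which left 3 residual degrees of freedom, to which the moderation added 4.09. Figures were drawn with matplotlib 3.10.9.

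A probe that was well above background on neither array of a population has only a bound there. Its fold is then given as "at least", from the mean of the brighter population and, for each array of the dimmer one, the higher of the lowest signal among probes well above background and the probe's own. Sizes of change are summarised with such probes at their bound. Where 1 of the 2 arrays was well above background, the fitted change is given with that number, and it rests in part on a value below background. The rule for named probes was set before the data were examined. Because no probe has a gene name, it took at most 2 higher and 2 lower probes per contrast, those with the largest fitted change among probes that passed the test. The fitted change of a probe below background in 1 population is not a measured size, so this order is that of the rule and not a ranking of measured changes. These also had to be well above background on both arrays of the higher population, saturated on no array and without overlap between the arrays of both populations. The sequences named for dd_smedV4_12179_0_1, dd_smedV4_60100_0_1 and dd_smedV4_10612_0_1 stood for 2, 2 and 5 transcript models, so their signal cannot be assigned to 1 model. Apart from these and dd_smedV4_566_0_1 (2 spots), each named probe had 1 spot per array.

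The procedure was tested on simulated data with the real probes' means and spread. Of 50 probes changed by 1, 2, 3 and 4 log2 units, it recovered 2%, 54%, 88% and 98% for X2 against X1. For Xins against X1 the shares were 2%, 60%, 90% and 98%, and for Xins against X2 they were 0%, 52%, 82% and 100%. Between 3 and 7 unchanged probes were called among the 2296. Each size was given to 50 probes only. The adjustment is less strict where more probes change, so the shares may be too low for a contrast with many more called probes.

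Whether the replicate numbers pair the arrays was checked from the differences between replicates 1 and 2. Over 2285 probes with a value on every array, these differences correlated between X1 and X2 (r = 0.603), X1 and Xins (r = 0.497) and X2 and Xins (r = 0.425). These are correlations across probes, which are not independent replicates. The numbers were therefore taken as pairing the arrays, although no label says what they mark, and counts from a fit with the replicate number as a block are given beside the others. The main counts, sizes and p-values stay those of the fit without the block, which had been set before the data were examined. Sizes of change were not summarised for the fit with the block.

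Alternatives set before the data were examined were quantile normalization, the array median, normexp background correction (offset 50), no filter on dim probes, a filter requiring all 6 arrays, the replicate block, the slide row as a block, a variance trend, the 4 arrays of each contrast alone, a minimum change of 1 log2 unit, the deposited value table, and leaving out each array in turn. Some further alternatives were added after seeing the data: probe names as units, a percentile over the 1685 probes well above background on all 6 arrays (also with the replicate block), scaling on 7 spike-in probes, normexp with a variance trend, the remaining filters, units and minimum change for the named probes, and the replicate block for probes that set 1 population apart. The percentile over commonly detected probes was added because at most 46.4% of the probes were well above background on any array.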

Results

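The series asked how transcripts ending at alternative polyadenylation sites are expressed as planarian stem cells give rise to differentiated cells. Planarians are flatworms that renew their tissues from a pool of dividing stem cells, called neoblasts. Sorting by DNA content and cell size gives the X1 fraction, which the labels describe as stem cells, the X2 fraction, described as progenitors, and the Xins fraction, described as differentiated cells. The worms were of the sexual strain. The labels name the arrays analysed here for proximal sites; the proximal site of a gene is the one that gives the shorter 3' untranslated region. The probes fell on 4977 sites of 3599 contigs. They were 45 to 60 nt long, with a median GC content of 22.4%. Since each transcript model had 1 probe, a difference in signal does not separate a change in transcript level from a change in the use of the site.

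Between 35.3% and 46.4% of the 5519 probes were well above background on an array. The number was 2471 and 1948 on X1 replicates 1 and 2, 2560 and 2082 on the X2 arrays, and 2234 and 2184 on the Xins arrays. Overall brightness differed more between arrays: the 75th percentile of signal was 69.7 and 23.1 intensity units for X1, 74.7 and 35.2 for X2, and 45.3 and 29 for Xins. Replicate 1 was thus the brighter array in each population. Most detected sites were seen in all populations. On both arrays of a population, 1937 probes were well above background in X1, 2043 in X2 and 2023 in Xins, and 1685 were so on all 6 arrays. Few sites were seen in 1 population alone: 14 probes were well above background on both X1 arrays and on no other array, 4 on the X2 arrays and 29 on the Xins arrays.

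The populations differed from each other by more than their replicates did. Across 2285 probes, the 2 arrays of a population correlated with r = 0.976 for X1, 0.963 for X2 and 0.955 for Xins. Arrays of X1 and X2 correlated with r between 0.903 and 0.922, those of X2 and Xins between 0.836 and 0.863, and those of X1 and Xins between 0.726 and 0.757. The first principal component held 71.5% of the variance and ordered the arrays X1, X2, Xins. The second, with 13.8%, set X2 apart from both others, and the third, with 9.91%, separated replicate 1 from replicate 2 in every population.

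**Figure D1:**
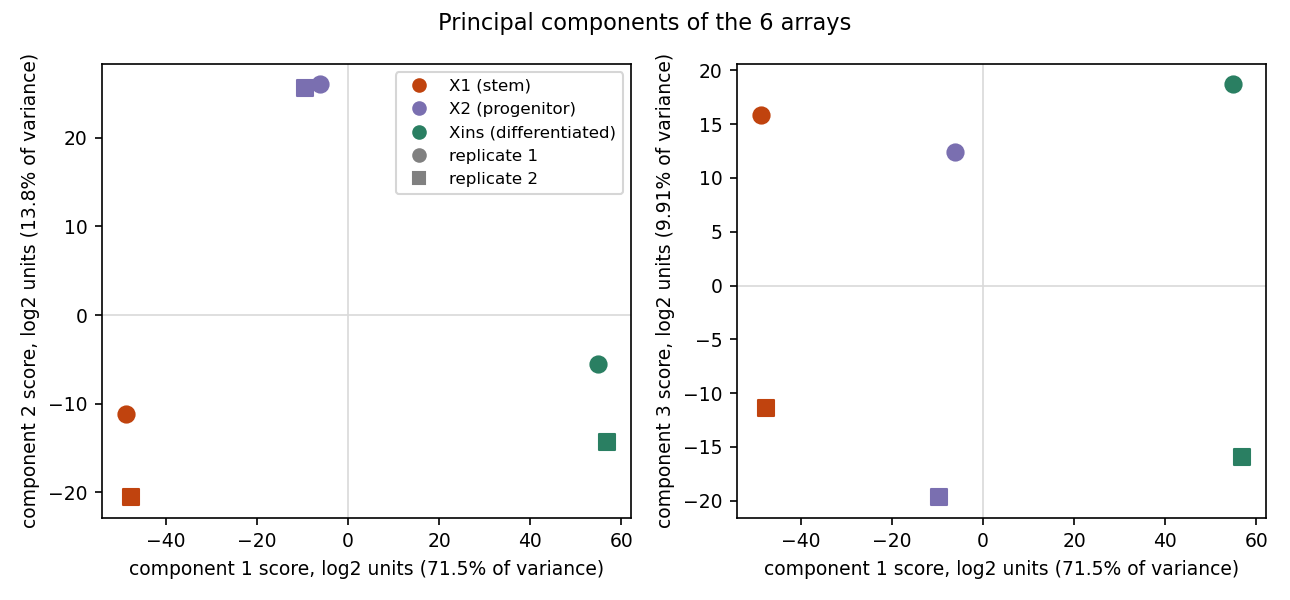
Scores of the 6 arrays on principal components 1 and 2 (left) and 1 and 3 (right), in log2 units, over 2285 probes; colour marks the population and shape the replicate. Component 1 (71.5% of the variance) runs from X1 (-48.61 and -47.51) through X2 (-6.11 and -9.526) to Xins (54.89 and 56.88), and component 3 (9.91%) is above 0 for each replicate 1 and below 0 for each replicate 2.

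Differentiated cells were first compared with stem cells. Signal differed between Xins and X1 at 1321 of 2296 tested probes (57.5%), which lay on 1162 sites; 556 probes were higher in Xins and 765 were lower. Sizes are given for called probes alone, so they leave out small changes. The simulated test of this contrast recovered 2% of changes of 1 log2 unit and 60% of those of 2. It held only 50 changed probes of each size, and the adjustment is less strict where more probes change. These shares may therefore be too low here, where 1321 probes were called. The median size was 2.4 log2 units (quartiles 1.68 and 3.5) for probes higher in Xins and 1.95 (quartiles 1.54 and 2.46) for those lower, with 112 and 115 probes at their bound. Among them, 344 were at least 4-fold higher in Xins and 361 at least 4-fold lower, while 96 were at least 16-fold higher and 22 at least 16-fold lower. The same contrast taken within replicate 1 and within replicate 2 correlated with r = 0.931 across probes, and 92.4% of probes had the same sign in both.

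By the rule for named probes, the rises in Xins over X1 with the largest fitted change were at sites of the transcript models mk4.000002.18.01 and dd_smedV4_12179_0_1. The first ends on contig 2, plus strand, at position 460797, with the probe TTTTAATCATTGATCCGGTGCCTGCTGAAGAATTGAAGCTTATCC. Its normalised log2 signal was -3.2 ± 1.4 in X1 (SD, n = 2, well above background on 1 of the 2 arrays), -1.79 ± 0.3 in X2 and 3.82 ± 1.3 in Xins, a rise of 7.03 (SE 0.796; limma adjusted p = 0.00083). The site of dd_smedV4_12179_0_1 lies on contig 1440, plus strand, from 5282 to 5287, with the probe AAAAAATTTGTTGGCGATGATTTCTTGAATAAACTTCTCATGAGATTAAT. It was not well above background on either X1 array, stood at -1.9 ± 0.31 in X2 and 2.48 ± 0.1 in Xins (SD, n = 2), and was at least 50.2-fold higher in Xins than in X1 (limma adjusted p = 0.00037). Of the falls, the rule took first the site of dd_smedV4_21323_0_1 on contig 3562, plus strand, from 40966 to 40977, with the probe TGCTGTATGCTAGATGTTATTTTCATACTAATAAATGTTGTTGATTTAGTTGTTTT. Its signal was 4.25 ± 0.15 in X1, 0.546 ± 0.77 in X2 and -1.26 ± 0.036 in Xins (SD, n = 2), a change of -5.51 (SE 0.443; limma adjusted p = 0.00037). The site of mk4.034612.00.01 on contig 34612, plus strand, at position 411 followed, with the probe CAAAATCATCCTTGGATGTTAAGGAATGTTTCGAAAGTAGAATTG. It went from 2.67 ± 0.32 in X1 through 0.141 ± 0.24 in X2 to -2.64 ± 1.9 in Xins (SD, n = 2), where 1 of the 2 arrays was well above background, a change of -5.31 (SE 0.81; limma adjusted p = 0.002).

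The median log2 difference over all tested probes was -0.465 for Xins against X1, -0.229 for X2 against X1 and -0.337 for Xins against X2, and every called probe lay on the same side of that median as of 0. Scaled on the probes detected on all 6 arrays, 53.8% of the called probes were higher in Xins than in X1 (672 higher, 577 lower), against 42.1% here, so which direction held more sites depended on the scaling. With the replicate block 1786 probes passed (720 higher in Xins, 1066 lower), and 1703 with the block and that scaling. With normexp background correction 44 probes passed and no named probe of any contrast did, without a filter on dim probes 585 passed, and with spike-in scaling 727. In the values the authors deposited 348 rows passed. What the columns of X1 replicate 2 and Xins replicate 2 hold is not known, so counts from those values, here and below, do not check the calls.

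Progenitors were next compared with stem cells. Fewer sites separated X2 from X1: 208 of 2296 probes (9.06%) on 181 sites passed the test, 132 higher in X2 and 76 lower. The median size of called probes was 2.5 log2 units (quartiles 1.75 and 3.4) for the higher probes and 2.1 (quartiles 1.81 and 2.55) for the lower ones, with 36 and 15 probes at their bound. At least 4-fold changes were found for 86 higher and 47 lower probes, and at least 16-fold changes for 17 and 3. The contrasts within each replicate number correlated with r = 0.852 across probes, with the same sign at 83.8%.

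The rule took 2 sites with a rise in X2 over X1 that were not well above background on either X1 array, so only a bound on their rise is known. That of mk4.000661.00.02 lies on contig 661, plus strand, from 32199 to 32244, with the probe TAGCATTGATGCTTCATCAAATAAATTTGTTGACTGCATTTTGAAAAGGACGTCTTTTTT. It stood at 1.16 ± 0.65 in X2 and 1.24 ± 0.1 in Xins (SD, n = 2) and was at least 20.2-fold higher in X2 than in X1 (limma adjusted p = 0.0045). That of mk4.000522.00.01 on contig 522, plus strand, from 8791 to 8927, with the probe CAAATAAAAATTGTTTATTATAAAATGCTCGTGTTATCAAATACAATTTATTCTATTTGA, stood at 0.134 ± 0.39 in X2 and -0.733 ± 0.9 in Xins (SD, n = 2). It was at least 9.91-fold higher in X2 than in X1 (limma adjusted p = 0.0086, and 0.055 without X2 replicate 2). Both sites taken for a fall in X2 were higher in Xins than in X2, and both passed the test in that contrast too. The site of dd_smedV4_60100_0_1 on contig 6, plus strand, from 49109 to 49120, has the probe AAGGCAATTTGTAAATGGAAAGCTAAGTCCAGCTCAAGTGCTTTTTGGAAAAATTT. Its signal was 3.16 ± 0.77 in X1, -2.58 ± 0.44 in X2 and -0.0092 ± 1.4 in Xins (SD, n = 2), a change of -5.75 from X1 to X2 (SE 0.692; limma adjusted p = 0.0062). The site of mk4.000985.12.01 on contig 985, minus strand, at position 54584 has the probe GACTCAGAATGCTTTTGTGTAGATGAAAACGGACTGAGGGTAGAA. Its signal was 1.72 ± 0.93 in X1, -3.57 ± 0.68 in X2 and 0.422 ± 1.9 in Xins (SD, n = 2), a change of -5.29 from X1 to X2 (SE 0.886; limma adjusted p = 0.014, 0.081 without X1 replicate 2 and 0.076 without X2 replicate 2). On X2, 1 of the 2 arrays was well above background for each of these 2 sites, so both changes rest in part on a value below background.

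With the replicate number as a block, 970 probes differed between X2 and X1, all 208 among them, of which 36.3% were higher in X2 against 63.5% here. The share was 79.9% when scaled on commonly detected probes (203 higher, 51 lower), 65.6% with that scaling and the block (813 probes), and 93.7% with spike-in scaling (127 probes), so no direction prevailed under all of them. The count was 38 without X2 replicate 2, 79 without X1 replicate 2, 83 without X1 replicate 1, 97 for probes detected on all 6 arrays, 392 with the slide row as a block, 6 with normexp, 77 in the values the authors deposited and 0 without a filter on dim probes (limma, 413 at an unadjusted p below 0.05).

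Differentiated cells were then compared with progenitors. Between Xins and X2, 723 of 2296 probes (31.5%) on 642 sites differed, 352 higher in Xins and 371 lower. The called higher probes had a median size of 2.51 log2 units (quartiles 1.87 and 3.34) and the lower ones of 1.54 (quartiles 1.3 and 1.82), with 39 and 68 at their bound. At least 4-fold changes were found for 242 higher and 52 lower probes, and at least 16-fold changes for 34 and 0. The contrasts within each replicate number correlated with r = 0.837 across probes, with the same sign at 89.2%.

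The site of dd_smedV4_566_0_1 on contig 6828, minus strand, from 2971 to 3014, was the first taken for a rise from X2 to Xins; its probe is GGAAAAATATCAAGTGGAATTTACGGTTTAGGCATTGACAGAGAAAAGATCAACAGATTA. Its signal was -1.64 ± 0.12 in X1, -1.7 ± 0.57 in X2 and 4.95 ± 0.64 in Xins (SD, n = 2), a rise of 6.65 over X2 (SE 0.464; limma adjusted p = 0.0038). The site of mk4.000002.18.01 came next, with a rise of 5.61 over X2 (SE 0.796; limma adjusted p = 0.0059). The sites taken for a fall were not well above background on either Xins array, so their fall is known only as a bound. That of dd_smedV4_9361_0_1 on contig 669, plus strand, from 58360 to 58368, with the probe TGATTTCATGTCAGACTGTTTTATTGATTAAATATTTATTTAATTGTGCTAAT, stood at -1.58 ± 0.59 in X1 and -1.28 ± 2 in X2 (SD, n = 2). It was at least 3.51-fold lower in Xins than in X2 (limma adjusted p = 0.027, 0.084 without X2 replicate 2 and 0.052 without Xins replicate 2). This bound rests on X2 replicate 2 (0.122), since X2 replicate 1 (-2.68) lay little above the lowest signals taken as well above background on the Xins arrays (-3.29 and -2.89). That of dd_smedV4_10612_0_1 on contig 10055, minus strand, at position 1813, with the probe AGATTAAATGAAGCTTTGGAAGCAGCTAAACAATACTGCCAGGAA, stood at -0.746 ± 0.53 in X1 and -0.783 ± 0.018 in X2 (SD, n = 2) and was at least 4.87-fold lower in Xins (limma adjusted p = 0.0092).

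With the replicate block, 1384 probes differed between Xins and X2, all 723 among them, with 38.2% higher in Xins against 48.7% here; scaled on the array median the share was 38.6% (262 higher, 416 lower). Leaving out 1 array moved the share the other way, to 74.2% without X2 replicate 2 (167 higher, 58 lower), 73.5% without Xins replicate 1, 71.5% without Xins replicate 2 and 62.1% without X2 replicate 1 or X1 replicate 2, so no direction prevailed under all of them. The count was 225 without X2 replicate 2, 425 without X2 replicate 1, 445 without Xins replicate 1, 233 with spike-in scaling, 44 in the values the authors deposited, and 0 both with normexp (limma, 328 at an unadjusted p below 0.05) and without a filter on dim probes (809). Without that filter the named probes of this contrast and of X2 against X1 did not pass.

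**Figure D2:**
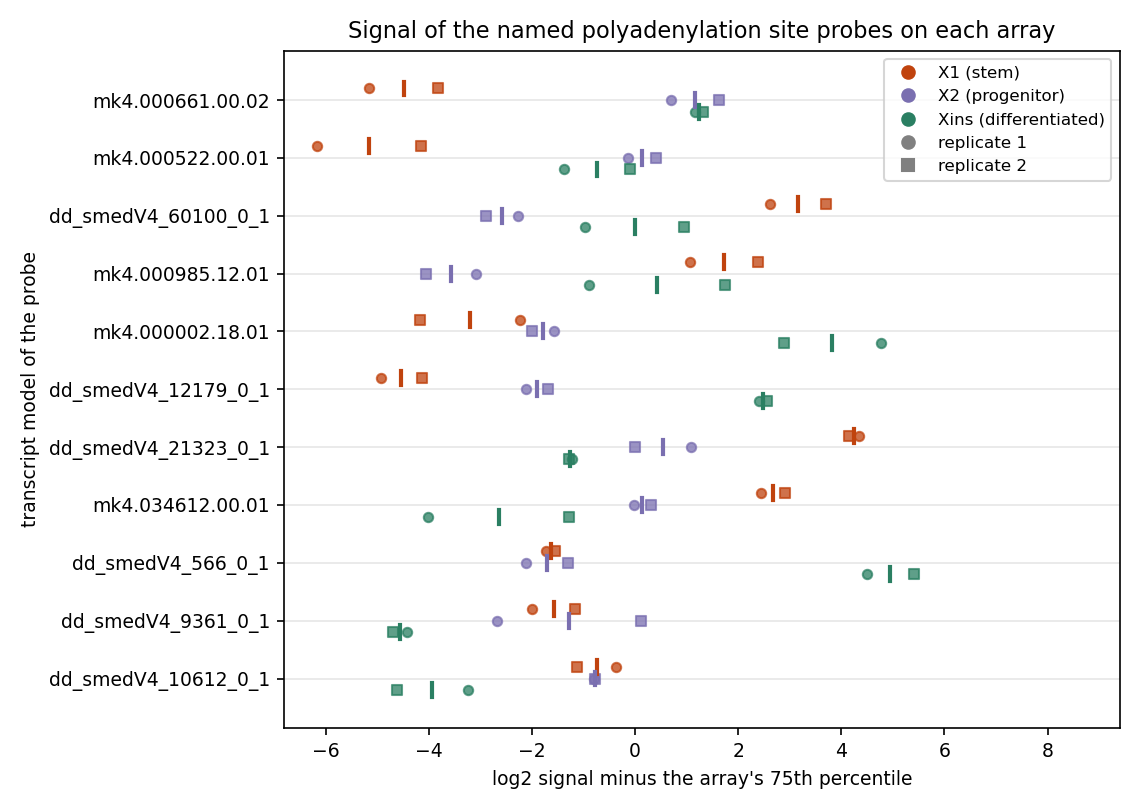
Normalised log2 signal (horizontal axis: log2 intensity minus the array's 75th percentile) of the 11 named probes (rows) on each of the 6 arrays; colour marks the population, shape the replicate and the short vertical bar the mean of 2 arrays. For each contrast that names a probe, the arrays of both populations do not overlap; X1 signal of mk4.000661.00.02, mk4.000522.00.01 and dd_smedV4_12179_0_1 and Xins signal of dd_smedV4_9361_0_1 and dd_smedV4_10612_0_1 was not well above background.

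Most sites that set 1 population apart from both others did so for X1 or Xins. Xins was higher than both X1 and X2 at 313 probes and lower than both at 335. X1 was lower than both others at 119 probes and higher at 61, while X2 was higher than both at 13 and lower at 14. Independent lists of the same lengths would share 85.2 and 124 probes for Xins, 32 and 25.3 for X1, and 21.3 and 11.7 for X2. These counts are from the fit without the replicate block. With the replicate block, Xins was higher than both others at 477 probes and lower at 780, X1 higher at 542 and lower at 310, and X2 higher at 54 and lower at 68. Independent lists would then share 166 and 397 probes for Xins, 287 and 110 for X1, and 131 and 142 for X2. In 100 simulations with no effect, the mean number over all these patterns was 0, and 0.12 with the block. Such simulations give few calls by construction, so they do not show how many probes to expect where other populations differ. Each pair of contrasts shares 2 arrays that could not be split, so part of the excess over independent lists may come from the shared arrays.

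Because the labels order the populations as stem, progenitor and differentiated cells, the place of X2 between the others was measured at the 1321 probes that differed between Xins and X1. On a scale where the X1 mean is 0 and the Xins mean is 1, X2 lay at a median of 0.394 (quartiles 0.241 and 0.539), and X2 replicates 1 and 2 taken alone gave 0.404 and 0.359. The X2 mean lay between the other means at 85.8% of these probes and nearer to X1 than to Xins at 69.6%. At probes lower in Xins, X2 was between the others at 95% (median position 0.42). At probes higher in Xins this held for 73.2% (median 0.328), with 17.3% at or beyond the X1 mean and 9.53% at or beyond the Xins mean. This split by direction was computed for the main scaling only. Scaled on commonly detected probes, the median log2 difference over tested probes moved from -0.229 to 0.13 for X2 against X1. For Xins against X1 it moved from -0.465 to -0.0701. Such a shift would move both positions in opposite ways, so the difference between the directions may depend on the scaling. At 112 of the probes higher in Xins, X1 was well above background on neither array. The same held for Xins at 115 of the probes lower in Xins. One end of the scale is only a bound at these probes, so their position is not a measured one. Probes are not replicates, so no p-value is given. The median over both directions together stayed below 0.5 under each alternative for which it was computed.

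**Figure D3:**
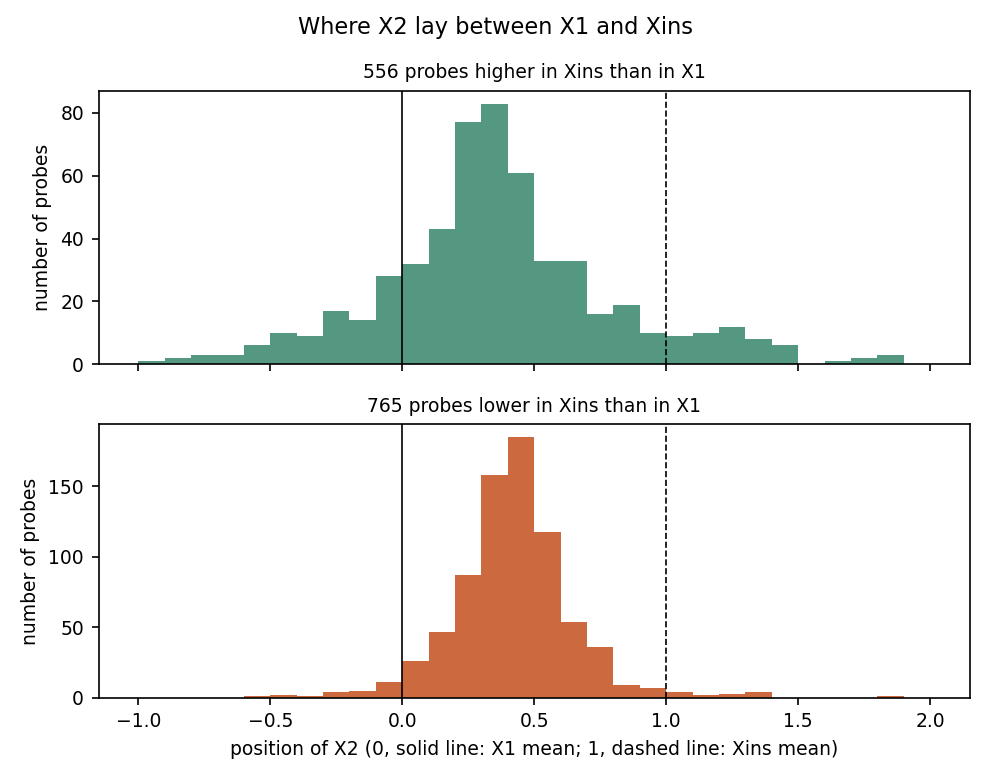
Histograms of the position of X2 (horizontal axis, no unit: 0 is the X1 mean, solid line, and 1 the Xins mean, dashed line; bins of 0.1) for 556 probes higher and 765 probes lower in Xins than in X1; the vertical axis counts probes, and 5 of the higher probes lie outside the axis. Both distributions peak between the lines, with medians of 0.328 and 0.42 under the main scaling. The X1 end was well above background on neither array at 112 of the probes higher in Xins, and the Xins end at 115 of those lower.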

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

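The alternatives added after seeing the data were probe names as units, the percentile over commonly detected probes, spike-in scaling, normexp with a variance trend, the replicate block with the percentile over commonly detected probes, the block for probes that set 1 population apart, and, for named probes, also the filters on dim probes and the minimum change. No setting run for them reversed any of the 12 named results: of 242 recomputed values 213 kept direction and significance and 29 kept their direction but did not pass. The named probes were chosen from these arrays without overlap between both populations, so leaving out 1 array could not reverse them. The replicate block, the variance trend, the 4 arrays alone, the filters and the minimum change left the log2 changes as they were. The lack of reversals was thus largely fixed in advance and is no support for these results. These 29 included all 12 under normexp. There almost no change was left at dd_smedV4_9361_0_1 (-0.0317, limma adjusted p 0.99) and little at dd_smedV4_10612_0_1 (-0.227, limma adjusted p 0.82). With a variance trend added to normexp, 8 of the 12 passed and 4 did not. The 29 also included 8 without a filter on dim probes (limma adjusted p 0.057 to 0.17), those of X2 against X1 and Xins against X2. The log2 changes of these 8 were those of the main fit, and only their adjusted p differed. Detection on all 6 arrays left 2 of the 12 to test, which passed. For X2 against X1, Xins against X1 and Xins against X2 in this order, the main counts of 208, 1321 and 723 became 6, 44 and 0 with normexp (116, 330 and 328 at an unadjusted p below 0.05) and 28, 156 and 80 with normexp and a variance trend. Normexp adds an offset of 50 to every spot, which by construction shrinks the changes of dim probes. This offset exceeds the 75th percentile of signal over all probes on X1 replicate 2 (23.1), X2 replicate 2 (35.2) and both Xins arrays (45.3 and 29). It therefore weighs on most probes there, not only on the dimmest. Without a filter on dim probes they were 0, 585 and 0 (limma, 413, 1331 and 809 at an unadjusted p below 0.05), with 5519 probes tested; with spike-in scaling 127, 727 and 233; and 77, 348 and 44 of 10871 rows for the authors' deposited values. Those values were fitted without a filter or scaling between columns. What the columns of X1 replicate 2 and Xins replicate 2 hold is not known, so these counts do not check the calls. Probe names as units gave 323, 2572 and 1271 of 4589, since several names share a sequence. The replicate block gave 970, 1786 and 1384, or 813, 1703 and 1374 with the percentile over commonly detected probes; it changed no named call. For X2 against X1, the slide row as a block gave 392 and detection on all 6 arrays 97. Leaving out 1 array gave 38 to 221, 934 to 1342 and 225 to 579; a population left with 1 array is then assumed to vary like the others. The position of X2 was 0.327 with quantile normalization, 0.356 with normexp and 0.302 with spike-in scaling, and 0.359 to 0.434 leaving out 1 array. The share of probes with X2 between the others was 84.2% with quantile normalization, 77.3% with normexp, 88.9% without a filter, 80.4% with the replicate block, 83.3% with the percentile over commonly detected probes, 81.2% with spike-in scaling, and 81.7% to 87.9% leaving out 1 array. Apart from the constructions named, the cause was not tested. Named probes were not recomputed from the authors' deposited values, whose rows match no probe. Tests of gene lists were not run, for want of gene names. Unequal change between the sites of a gene was not tested either, since the files state no pairing of transcript models with genes. Whether the model names could serve to group them was not examined. Signal over background limits the dim sites: the 75th percentile of X1 replicate 2 was 23.1 intensity units.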

Other observations

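The test of the slide row was chosen after its result was seen, and the classes of probes described here were chosen after the data were examined.

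Probes that held the polyadenylation signal AATAAA had a lower median log2 difference in Xins against X1 than other probes, a shift whose test did not hold with an estimated correlation (adjusted p = 0.52). AATAAA is the main motif that directs cleavage and polyadenylation of animal transcripts shortly downstream of it. It was present in 1892 of 5519 probes (34.3%). In 1330 such probes shorter than 60 nt, the motif ended 10 to 14 nt from the probe's 3' end in 18.8%, 15 to 19 nt in 51.8% and 20 to 24 nt in 21.8%. Of the 604 tested probes with AATAAA, 268 (44.4%) were lower and 102 (16.9%) higher in Xins than in X1. Of the 1692 without it, 497 (29.4%) were lower and 454 (26.8%) higher. Their median log2 differences were -0.965 and -0.203. Median normalised log2 signal of the AATAAA probes was 1.02 in X1, 0.622 in X2 and 0.398 in Xins, against 0.698, 0.771 and 0.816 for the other probes.

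The median of AATAAA probes minus that of other probes was thus -0.762 in Xins against X1, the lowest of 199 hexamers found in at least 100 tested probes. Its bootstrap SE of 0.12 came from resampling probes with the 6 arrays held fixed. That SE treats probes as independent and measures no spread between arrays. Other AT-rich hexamers lay within 0.12 of AATAAA (TAAATA -0.719, ATAAAT -0.691, GTAAAT -0.689, GTATTT -0.688), so the rank alone does not single out AATAAA. Some of these hexamers overlap AATAAA in sequence, and probes holding AATAAA were not removed. Their values are therefore not independent of it, and the ranking cannot decide whether AATAAA is special. With limma's camera and its preset correlation the class was shifted (adjusted p = 0.014, 9 tests), but not with an estimated correlation (adjusted p = 0.52; 0.38 in the fit with the replicate block, 3 tests). GC content and length, brightness and a single array are argued against as the whole cause: the difference was -0.771 within strata of GC and length, -0.842 within strata of signal, -0.652 within joint strata of GC and signal (below 0 in 16 of 18), and at most -0.685 when any 1 array was left out. Among probes under 60 nt, those with AATAAA 10 to 30 nt from the 3' end differed from the 10 with it elsewhere by -0.489. The bootstrap SE, again over probes, was 0.88, and 10 probes were too few to tell whether the motif's place matters. The difference was -0.777 with quantile normalization and -0.208 with normexp background correction. The offset of normexp shrinks changes of dim probes by construction, so its value does not test whether background treatment made the difference, and nothing else here does. That sites with AATAAA may be used or expressed less in differentiated cells is a hypothesis.

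Replicates 1 and 2 differed in a like way in all 3 populations, with correlations of 0.425 to 0.603 between populations across probes. After a smooth trend on mean signal was removed the lowest correlation was 0.404, and after a trend on GC content and length 0.457, which argues against either trend as the whole cause. The slide row is argued against as the whole cause as well, since both Xins arrays lay in row 2 and their difference still correlated with that of X1 (0.497). A part played by the row is not excluded. The correlation was highest (0.603) between X1 and X2, whose replicates lay in different rows. A sort, amplification or labelling batch shared by same-numbered arrays may remain, but no label gives one, and no biological explanation was tested.

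Changes of neighbouring sites on a contig in Xins against X1 correlated past the threshold in 1 class of pairs by distance. Of the 7 tests adjusted for, 2 held the same 27 pairs on opposite strands, so 1 class was counted 2 times. Log2 differences correlated with r = 0.31 (Spearman 0.258) across 123 pairs 10 to 50 kb apart (permutation p = 0.00055, adjusted 0.0038 over 7 tests), yet only 54.5% of these pairs had the same sign. The value was 0.186 for 51 pairs 1 to 10 kb apart (permutation p = 0.19, adjusted 0.33; 58.8% with the same sign), 0.886 for 5 pairs up to 1 kb apart (permutation p = 0.046, adjusted 0.14) and 0.0792 for 98 pairs over 50 kb apart (permutation p = 0.44, adjusted 0.62). Pairs within 10 kb on opposite strands, which cannot be models of 1 gene, gave r = 0.0711 over 27 pairs (95% interval -0.317 to 0.439), and those on the same strand 0.354 over 29 pairs (-0.0144 to 0.638). No class of pairs within 10 kb passed after adjustment, so no correlation was established there. Whether neighbouring genes share their change or models of 1 gene end at several sites cannot be told apart with so few pairs. Neither was tested for the pairs 10 to 50 kb apart.

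At 342 sites with 2 tested probes of different sequence, the log2 differences of the 2 probes correlated with r = 0.947 for X2 against X1, 0.976 for Xins against X1 and 0.974 for Xins against X2. Both probes passed the test in the same direction at 27, 159 and 81 sites and in opposite directions at 0 in each contrast. The difference between the 2 probes itself changed at 0, 11 and 1 of 336 sites (limma adjusted p; 34, 52 and 22 at an unadjusted p below 0.05). Both probes of a site had the same contig, strand, start and end and were read on the same arrays. How far their sequences differed was not examined, so their agreement is not independent support for the changes.

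Detection rose with the GC content of the probe. Of the 637 probes with up to 15% GC, 1.57% were well above background on all 6 arrays, against 33% of the 1393 probes with 20 to 25% and 69.6% of the 181 with over 40%.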
